A study of Arabidopsis thaliana with 6 samples.

How the data were processed

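The series holds 3′ RNA-seq of total RNA from whole seedlings of Arabidopsis thaliana, 6 libraries in 2 genotypes. In 3′ RNA-seq the reads come from the end of a transcript, so a count does not grow with transcript length. Per the labels, seedlings had 16 h of light at 150 µmol photons per m2 and s and 8 h of dark for 14 days, RNA had an integrity number above 8, 1 µg went into each library, and primers carried a molecular identifier of 6 bp. The design text of the series calls the libraries independent biological replicates. It does not say how many independent lines of amiRNA-VQ1,10 were used.

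The deposited values are raw counts per gene, whole numbers with no normalization, in a file per library. Per the submitters' processing notes, the build was TAIR10 and the tools were STAR, HISAT2 2.0.4 and DESeq2, with no role or order given. Which program made the counts, its strand setting and whether reads with the same molecular identifier were collapsed are not given in the sources used here. Intervals and floors therefore cover counting error only. For genes that overlap a gene on the opposite strand, it is not known whether reads in the overlap were assigned to a gene or set aside. Among the genes named here that were looked up, such an overlap was found for AT3G15450, IMA3, RAB18, DIN10, F3H, UGT75C1, ADH1 and HUP54. Overlaps were not looked up for VQ1, VQ10, MIR390a, AT4G11655, CCA1, LHY, GI, PRR7 and HB17. Of the 13 genes past the threshold 1 overlaps another annotated gene. Entries that name no gene stayed out of totals and tests. Reads outside genes made up 3.79% to 4.07% of the entries of a library, reads in more than 1 gene 0.103% to 0.109%, and reads with more than 1 alignment 4.40% to 5.45%.

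Gene names came from the RefSeq annotation of TAIR10.1, used for names, for overlaps and for which genes are neighbours, with no coordinates. Of 32833 gene identifiers 32548 matched and 285 did not. Counts were present for 22738 genes. The filter of edgeR 4.0.16 (filterByExpr, minimum count 10, minimum total 15) left 12701 genes, with a median of 29.1 CPM.

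The 2 genotypes were compared with the quasi-likelihood test of edgeR on TMM-scaled counts, in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Log2 fold changes are amiRNA-VQ1,10 over wild type. SE is the log2 fold change over the square root of the F statistic. Gene lists were tested with camera in limma 3.58.1 on log-CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 30 lists. Camera with an estimated correlation and the directional test of fry were run beside it. Of 33 lists, root hairs, floral transition and seed storage had fewer than 5 tested members and were not tested. From the lists 3 entries were left out because the reference gives the symbol to another gene, and 1 because the files do not hold it. VQ1 and VQ10 were examined from their counts, with a floor of 3 counts over the libraries of a genotype.

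The groups, the gene lists, the comparison with its tests, the rule for named genes and the alternatives apart from thinning were fixed before the data were examined. The closing section names the further tests that were chosen afterwards. The rule names VQ1 and VQ10, other VQ genes past the threshold, in each direction the 12 nuclear genes with the largest change and the 5 with the smallest p among those past the threshold, with separate ranges and at least 5 CPM, and up to 4 genes with the smallest p per list. VQ19 comes from its list. MIR390a and AT4G11655, in the closing section, were chosen after their values were seen.

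Replicate libraries of a genotype differed by more than sampling noise, with a chi-square per degree of freedom of 1.27 to 1.66. The first principal component (26.9% of the variance) set apart amiRNA-VQ1,10 replicate 2, the library with the lowest total. The shared coefficient of variation was 0.0727. On simulated data with 3 libraries per genotype and 200 changed genes among 12701, of which 12342 were tested, the test called 24% of genes changed 1.5-fold, 72% at 2-fold and 94% at 4-fold and at 8-fold, and 3.92% of its 153 calls were unchanged genes. The calls include members of a list of 15 other genes shifted by 0.7, counted as changed. For that list camera gave an adjusted p of 3.6e-15 with the preset correlation and 0.0511 with an estimated one. Simulated genes were drawn independently of each other, each with the spread of a shared trend. In the data the estimated correlation differed by list, with 0.63 for iron deficiency and -0.02 for cold response. The simulation therefore cannot tell which correlation suits the real lists, and its shares of called genes may be too favourable.

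The alternatives were other scalings, no filter and a strict filter of 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, organelle genes left out, an adjusted p under 0.01, tissue lists left out, and each library left out in turn. Thinning all libraries to the lowest total was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.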

Results

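Transcript counts were collected from whole seedlings of Arabidopsis thaliana in 2 genotypes, with 3 libraries each. Wild type Col-0, the standard laboratory accession, was set against amiRNA-VQ1,10, a line that carries an artificial microRNA named for VQ1 and VQ10. An artificial microRNA is a designed small RNA meant to lower transcripts that match it, and the VQ family is a group of plant proteins known to bind WRKY transcription factors. All seedlings were grown in normoxia (21% O2) for 14 days with 1% sucrose and were harvested 4 h after lights on. The totals over genes were 1175811, 1329817 and 1124134 counts in the wild type libraries. They were 1104916, 926209 and 1177363 counts in the amiRNA-VQ1,10 libraries. The median tested gene had 32.2 counts per library. The comparison asks how gene expression in normoxia differs between the line and wild type.

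Counts of VQ1 (AT1G17147) were 5, 1 and 2 in the wild type libraries and 0, 0 and 0 in the amiRNA-VQ1,10 libraries. VQ1 stood at 2.25 CPM over the wild type libraries, with an exact Poisson 95% interval of 0.972 to 4.44 CPM. The wild type value was 2.33-fold above the floor of 3 counts over the amiRNA-VQ1,10 libraries (0.967 CPM). This ratio leaves out the counting error in wild type, where the lower limit of 0.972 CPM lies next to the floor. A two-sided exact binomial test on the reads of these libraries gave p = 0.00883, and a two-sided exact permutation test over the 6 libraries gave p = 0.1, the smallest that 3 against 3 can give. Of the 8 wild type counts of VQ1, 5 were in replicate 1. Without that library VQ1 had 3 counts, at the floor, so that no fold can be given (exact binomial p = 0.0833). Without amiRNA-VQ1,10 replicate 1 or 3 the ratio to the floor was 1.53-fold and 1.47-fold (exact binomial p = 0.0312 and 0.0572). VQ10 (AT1G78410) had 1 count in wild type replicate 1 and 0 in the other libraries, so a difference in VQ10 was not detectable at this depth. Neither gene had enough counts to pass the filter. In the edgeR fit with no filter neither passed, with log2 fold changes of -4.40 ± 1.66 for VQ1 (SE, adjusted p = 0.522) and -1.81 ± 2.13 for VQ10 (adjusted p = 0.908), values that depend on the prior count. Of the 34 VQ genes listed, 10 were tested and none passed. The list as a whole did not pass either (camera adjusted p = 0.363). VQ19 had the smallest p, with a log2 fold change of -0.87 ± 0.32 (SE, n = 3 per genotype, edgeR adjusted p = 0.574).

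The amiRNA-VQ1,10 seedlings had far lower levels of QQS and of several noncoding RNAs, and a higher level of AT3G07890. QQS (AT3G30720), an orphan gene known to affect leaf starch, fell from 259 ± 19.5 to 27.8 ± 4.77 CPM (SD, n = 3), a log2 fold change of -3.21 ± 0.14 (SE). The noncoding RNA AT2G01422 fell from 87.0 ± 10.7 to 3.45 ± 2.83 CPM. The noncoding RNA AT4G04223 fell from 28.2 ± 1.29 to 2.19 ± 0.938 CPM, and AT1G67105 fell from 58.6 ± 1.87 to 14.1 ± 4.18 CPM. AT3G07890, annotated with a Ypt/Rab-GAP domain, rose from 8.62 ± 3.19 to 73.1 ± 3.48 CPM.

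In all, 13 of 12701 tested genes passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 3 rose and 10 fell, and 12 differed by at least 2-fold. AT3G15450, annotated as an aluminium-induced protein with YGL and LRDR motifs, rose by 1.14 ± 0.16 on the log2 scale (adjusted p = 6.8e-04). For QQS, AT2G01422, AT3G07890, AT4G04223 and AT1G67105 the adjusted p lay between 3.5e-13 and 2.3e-06. These 5 genes and AT3G15450 were the 6 genes called also in each fit with a library left out, by DESeq2 and by limma-voom. The other 7 genes passed less firmly. RD29B (also LTI65, AT5G52300), induced by abscisic acid and drought, fell from 46.9 ± 34.2 to 4.99 ± 2.11 CPM (adjusted p = 0.00798). bHLH39 (AT3G56980), a transcription factor that activates iron uptake genes, fell by 1.14 on the log2 scale (adjusted p = 0.0478). SAG29 (AT5G13170), a sugar transporter of the SWEET family linked to senescence, fell by 0.55 (adjusted p = 0.0372). AT3G56210, AT2G41190 and the noncoding RNA AT4G14548 had log2 fold changes of -1.11, -1.13 and -1.56, past the threshold, and AT4G01870 rose by 1.08. All 13 genes had separate ranges in the 2 genotypes. Among the tested genes 1321 (10.4%) did, where chance gives 10%. At an unadjusted p under 0.05 there were 765 genes.

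The count of genes depended on the fit: DESeq2 called 6, limma-voom 8, a strict filter 6, no filter 92, the fit without wild type replicate 2 called 37 and the fit without amiRNA-VQ1,10 replicate 3 called 22. The number that rose was 6 without wild type replicate 2, 10 without amiRNA-VQ1,10 replicate 1 and 8 without amiRNA-VQ1,10 replicate 3. The number that fell was 31 and 4 without the first and second of these. RD29B lost its call without amiRNA-VQ1,10 replicate 1 (adjusted p = 0.0529), by DESeq2 (0.214) and by limma-voom (0.356). bHLH39 lost it without wild type replicate 1 (0.296), amiRNA-VQ1,10 replicate 1 (0.253) or amiRNA-VQ1,10 replicate 2 (0.0731), by DESeq2 (1.00) and limma-voom (0.113), with a strict filter (0.0925) and with the replicate number as a block (0.0803). AT3G56210 lost it without wild type replicate 1 or 3 (0.0540 and 0.0876) or amiRNA-VQ1,10 replicate 1 (0.120), and by DESeq2 (0.174). SAG29 lost it without wild type replicate 1 or 3 (0.0964 and 0.189) or amiRNA-VQ1,10 replicate 1 or 2 (0.149 and 0.109), by DESeq2 (0.0604) and with a strict filter (0.0507). AT4G01870 lost it without wild type replicate 1 or 3 (0.0819 and 0.107) or amiRNA-VQ1,10 replicate 2 or 3 (0.0959 and 0.116), by DESeq2 (1.00) and limma-voom (0.153), and with a strict filter (0.0925). AT4G14548 kept it only without wild type replicate 3 among the 6 such fits, with adjusted p of 0.0731 to 0.296 in the others. AT2G41190 kept it only without wild type replicate 2, with 0.0584 to 0.225 in the others. By DESeq2, limma-voom and with the block AT4G14548 had adjusted p of 0.651, 0.160 and 0.0929, and AT2G41190 had 0.294, 0.122 and 0.0599. With libraries thinned to the lowest total, AT3G56210 and AT2G41190 were not called.

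**Figure D1:**
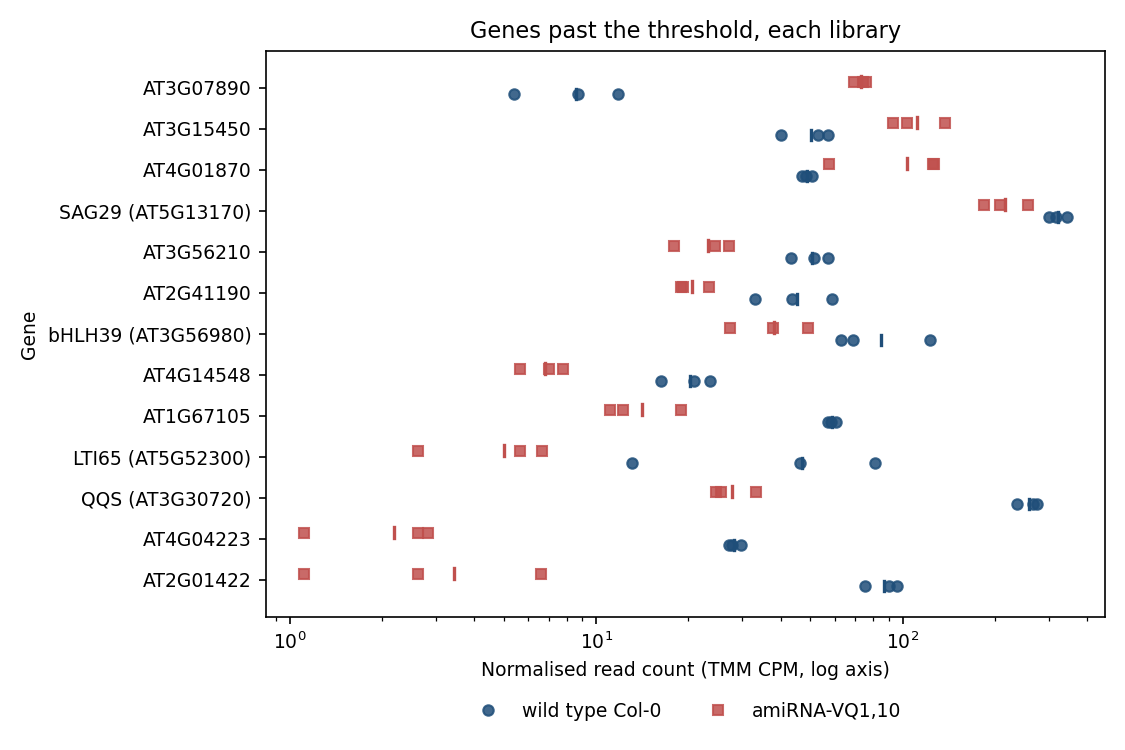
Normalised read counts (TMM CPM, log axis) of the 13 genes past the threshold, with a point per library (circles wild type Col-0, squares amiRNA-VQ1,10) and a bar at each mean of 3. QQS sits near 259 CPM in wild type and 27.8 CPM in amiRNA-VQ1,10, and AT3G07890 near 8.62 and 73.1 CPM.

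By camera with the preset correlation of 0.01, genes of the iron deficiency and abscisic acid responses were lower in amiRNA-VQ1,10 as groups. By the same test genes of sugar starvation were higher. All 3 calls were lost with the estimated correlations, which were 0.63, 0.49 and 0.33 in this order. They were lost in fry too (adjusted p = 0.48 for each). Cold response and expansins lost their calls with estimated correlations near 0 (-0.02 and 0.03). In the simulation a shifted list of independent genes also missed the threshold by this form of camera (adjusted p = 0.0511). A call lost with an estimated correlation therefore does not show that correlation among the genes produced the preset call. All 15 tested iron deficiency genes had a log2 fold change below 0 (median -0.77; camera adjusted p = 1.0e-09), and 1 fell over all genes tested, 13 adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.53 with an estimated correlation). Beside bHLH39, the lowest p values were those of IMA3 and IMA2, peptides that promote iron uptake, at -0.79 ± 0.18 and -0.998 ± 0.24, and of CYP82C4, an enzyme of coumarin synthesis, at -0.92 ± 0.21 (SE). None of these 3 passed over all genes. IMA3 passed without wild type replicate 2 or 3 (adjusted p = 0.0162 and 0.0194), CYP82C4 without wild type replicate 2 or 3 or amiRNA-VQ1,10 replicate 3 (0.0360, 0.0153 and 0.0218), and IMA2 without wild type replicate 2 or amiRNA-VQ1,10 replicate 3 (0.00187 and 0.0409). Without wild type replicate 1 the log2 fold changes were -0.45 for IMA3, -0.53 for CYP82C4 and -0.55 for IMA2 (adjusted p = 0.646, 0.763 and 0.901). The mean over the list was -0.76, and -0.41 without wild type replicate 1. That library scored 0.93 on the list, against 0.04 and 0.11 in the other wild type libraries. The amiRNA-VQ1,10 libraries scored -0.67, -0.37 and -0.04. The 6 tested markers of the root endodermis and root tissues had a median of 0.01 (camera adjusted p = 0.75).

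All 16 tested genes of the abscisic acid and osmotic stress list were below 0 (median -0.38; camera adjusted p = 1.5e-08; adjusted p = 0.53 with an estimated correlation). Over all genes tested 1 of them, RD29B, fell, and 8 did so adjusted over the list alone. RAB18, a dehydrin, stood at 277 ± 224 CPM in wild type and 99.9 ± 20.4 CPM in amiRNA-VQ1,10 (adjusted p = 0.113; 0.0159 without wild type replicate 1 and 0.00102 without wild type replicate 2). Its CPM in wild type replicate 3 was 535, against 163 and 133 in the other wild type libraries. Without replicate 3 its log2 fold change was -0.55 (adjusted p = 0.302), against -1.44. That library also had the highest score of the list, 0.61 against 0.20 and 0.13. RD20, a caleosin, had a log2 fold change of -0.51 ± 0.12 and NCED3, a key enzyme of abscisic acid synthesis, one of -1.16 ± 0.36. With a strict filter the mean of the list was -0.41, against -0.67. RD29B and NCED3 had too few counts for that fit, so its mean leaves them out. All 7 tested genes of the cold list, which shares targets with dehydration, were below 0 as well (median -0.35; camera adjusted p = 8.4e-04; adjusted p = 0.52 with an estimated correlation). None of the cold genes passed over all genes and 3 fell adjusted over the list alone: ERD10 (-0.48 ± 0.13), COR15A (-0.51 ± 0.16) and LTI30 (-0.43 ± 0.15). Without a filter the mean of the cold list was -0.21, against -0.33, and it may cover further members with few counts.

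All 13 tested genes of the sugar starvation list were above 0 (median 0.63; camera adjusted p = 1.1e-06; adjusted p = 0.53 with an estimated correlation). None passed over all genes and 5 rose adjusted over the list alone. SEN1, a gene induced in darkness, stood at 8.00 ± 3.23 CPM in wild type and 31.6 ± 23.4 CPM in amiRNA-VQ1,10 (adjusted p = 0.0999). SEN1 passed without wild type replicate 2 or amiRNA-VQ1,10 replicate 1 (0.0499 and 0.00695), and DIN10 without amiRNA-VQ1,10 replicate 1 (0.0462). The CPM of SEN1 was 57.9 in amiRNA-VQ1,10 replicate 2, the highest of the 3 amiRNA-VQ1,10 libraries, and lowest in replicate 1 with 13.2. Without replicate 2 its log2 fold change was 1.18 (adjusted p = 0.529), against 1.88. That library, which the first principal component sets apart, also had the highest score of the list, 0.63 against -0.04 and 0.25, and the mean of the list was 0.41 without it, against 0.61. DIN10, TPS11 and BZIP1, known to respond to low sugar, had log2 fold changes of 0.93 ± 0.26, 0.71 ± 0.22 and 0.63 ± 0.22 (SE).

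Of the 16 tested genes of phenylpropanoids and flavonoids 14 were below 0 (median -0.47; camera adjusted p = 3.4e-04; adjusted p = 0.94 with an estimated correlation), and none fell over all genes, 5 adjusted over the list alone. The anthocyanin genes F3H, LDOX, DFR and UGT75C1 had log2 fold changes of -0.38 ± 0.11, -0.67 ± 0.20, -0.55 ± 0.20 and -0.69 ± 0.26. The call of the list was lost without wild type replicate 1 (mean -0.18, adjusted p = 0.13), where LDOX, DFR and UGT75C1 stood at -0.39, -0.18 and -0.35. DFR passed without wild type replicate 2 (0.0249). Of the 44 tested nuclear genes of light harvesting and the photosystems 41 were above 0, by little (median 0.08; camera adjusted p = 0.00686; adjusted p = 0.94 with an estimated correlation). None rose over all genes and 1 adjusted over the list alone, LHB1B1, a chlorophyll-binding protein, at 0.40 ± 0.09, which passed without amiRNA-VQ1,10 replicate 2 or 3 (adjusted p = 0.0268 and 0.00872) and stood at 0.27 without amiRNA-VQ1,10 replicate 1 (0.324). Of the 65 tested chloroplast genome transcripts 48 were below 0 (median -0.13; camera adjusted p = 8.9e-04; adjusted p = 0.94 with an estimated correlation), with 0 past the threshold over all genes and 0 adjusted over the list alone. Of the 16 tested genes of expansins and xyloglucan remodelling, which loosen cell walls, 12 were above 0 (median 0.13; camera adjusted p = 0.0462; adjusted p = 0.53 with an estimated correlation). None rose over all genes and 2 did adjusted over the list alone, XTH24 (0.79 ± 0.22, and 0.38 without amiRNA-VQ1,10 replicate 2) and EXPA1 (0.28 ± 0.09). The light harvesting call was lost without wild type replicate 1, amiRNA-VQ1,10 replicate 1 or amiRNA-VQ1,10 replicate 3 (adjusted p = 0.0983, 0.184 and 0.125), and the chloroplast call without wild type replicate 2 or amiRNA-VQ1,10 replicate 3 (0.216 and 0.398). The chloroplast mean was -0.14, and it was -0.05, -0.08 and -0.21 without wild type replicate 2, amiRNA-VQ1,10 replicate 3 and amiRNA-VQ1,10 replicate 1. The expansin call was lost without wild type replicate 2 or 3 or amiRNA-VQ1,10 replicate 1 or 3 (adjusted p = 0.0643, 0.312, 0.184 and 0.125). It was also lost with no filter (0.0773), a strict filter (0.0918), organelle genes left out (0.0504) and libraries thinned to the lowest total (0.134).

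**Figure D2:**
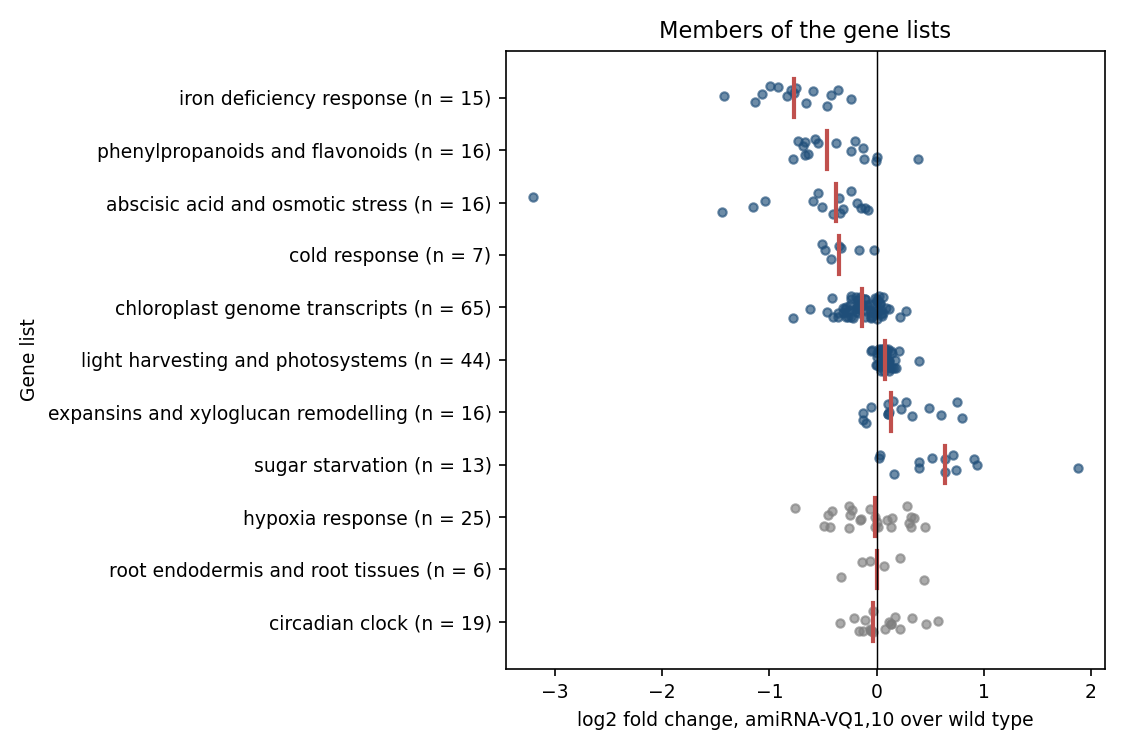
Log2 fold changes of the tested members of 11 gene lists (amiRNA-VQ1,10 over wild type), with a point per gene and a bar at each median; n is the number of tested members. The 8 lists past the threshold are in blue, and 3 lists that did not pass are in grey, among them hypoxia response with a median of -0.01.

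In all, 8 of 30 tested lists passed with the preset correlation of 0.01 (5 without amiRNA-VQ1,10 replicate 3), and 0 passed with an estimated correlation or in fry, a test of each list by itself. The hypoxia list, 25 tested genes induced when oxygen is low, did not pass (median -0.01; camera adjusted p = 0.65). ADH1 and PDC1, the enzymes of ethanolic fermentation, had log2 fold changes of -0.42 ± 0.22 and -0.43 ± 0.23, and HUP54 one of 0.45 ± 0.14 (SE, edgeR adjusted p = 0.43). PDC1 stood at -0.27 without wild type replicate 1. Oxygen sensing by the N-degron pathway did not pass either (8 tested genes, median 0.05, adjusted p = 1.00). The list of heat shock and protein folding had a median of 0.27 without passing (17 tested genes, adjusted p = 0.0892). Per library the heat shock list scored 0.81 in amiRNA-VQ1,10 replicate 3, and its mean was 0.01 without that library. It was called on limma-voom values of all 6 libraries (camera adjusted p = 0.00501), and on log-CPM without wild type replicate 1 (adjusted p = 0.00516), amiRNA-VQ1,10 replicate 1 (8.4e-04) or amiRNA-VQ1,10 replicate 2 (0.0182), within a range of 8.4e-04 to 0.941 over all alternatives.

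Apart from abscisic acid, the hormone and defence lists did not pass. Their medians were -0.25 for salicylic acid defence, -0.04 for jasmonate, 0.13 for ethylene, 0.04 for auxin and 0.06 for rapid wound and elicitor response. Salicylic acid defence passed without wild type replicate 3 (adjusted p = 0.0190). The medians were -0.07 for camalexin and indolic glucosinolates and -0.02 for aliphatic glucosinolates. Chlorophyll synthesis (0.06), nitrate (0.02), phosphate starvation (0.02), mitochondrial stress (0.02), cell division (0.06), leaf senescence (-0.05), the circadian clock (-0.03) and the VQ family (-0.10) had medians that did not pass either. Among tissue markers, the vascular (0.23), stomatal (-0.03) and mitochondrial genome (-0.03) lists did not pass. In leaf senescence, SAG29 fell over all genes, and adjusted over the list alone 1 gene rose and 1 fell. The heat shock and nitrate lists each had 1 gene that rose adjusted over the list alone. Median, mean and test differed in sign for the phosphate, clock, mitochondrial genome, senescence, mitochondrial stress and oxygen sensing lists.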

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

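The test on other microRNA precursors was chosen after the result was seen, and its wording was tightened then too. MIR390a (AT2G38325), a microRNA precursor outside the genes tested, had 13 counts in the amiRNA-VQ1,10 libraries (7, 1 and 5) and 0 in all wild type libraries. The amiRNA-VQ1,10 value was 4.96-fold above the floor of 3 counts over the wild type libraries. This ratio leaves out the counting error of the 13 counts. A two-sided exact binomial test on the reads of these libraries gave p = 4.9e-05, and 0.492 after Bonferroni correction over the 10037 untested genes with counts. The MIR390a pattern may be chance among genes with few counts, since 5 of the 10 splits of the 6 libraries, the real one included, gave as many genes with 10 or more counts on one side, seen in each of its libraries, and none on the other (2 in the real split, and up to 5 in another). AT4G11655 was the opposite case, with 10 counts in wild type and 0 in amiRNA-VQ1,10. Whether these are transcripts of the amiRNA transgene stays open: 0 other annotated microRNA precursors showed the pattern, but 58 of the 325 had a count in any library, so this count decides nothing, and the backbone of the construct is not given in the sources used here.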

How the results depend on the processing

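Thinning the libraries was chosen after the data were seen; the other alternatives were chosen before. Thinning was run for the counts and the lists, with no value per gene. No named gene changed direction under the other alternatives that tested it. QQS, AT2G01422, AT3G07890, AT1G67105 and AT3G15450 were called in each fit, and AT4G04223 in each fit that tested it. Thinning aside, gene values lost the call in 43 cases and gained it in 31. List values, thinning included, lost it in 30 and gained it in 5. The cold, abscisic acid, iron deficiency and sugar starvation lists were called in each fit with the preset correlation that tested them, and the strict filter did not test sugar starvation. An adjusted p under 0.01 left 7 genes (5 fell, 7 at least 2-fold). Camera with an estimated correlation and the directional test of fry each left 0 lists. With no filter 92 genes passed (44 rose, 48 fell, 37 at least 2-fold), all 13 among them: the prior degrees of freedom of edgeR went from 19.4 to infinity, so each gene took the spread of the trend. Among named genes RAB18, SEN1, IMA3, CYP82C4, IMA2, RD20, ERD10, XTH24, DIN10, LDOX, DFR and LHB1B1 were past the threshold there, and RAB18, SEN1 and LHB1B1 with the replicate number as a block. A strict filter left 6 genes (4 fell, 6 at least 2-fold), with 4594 genes tested. DESeq2 gave 6 (4 fell, 6 at least 2-fold) and limma-voom 8 (6 fell, 7 at least 2-fold). With the replicate number as a block 6 rose, 16 genes in all, though the numbers do not pair the samples. With a library left out, 10 to 37 genes passed, 3 to 10 rose, 4 to 31 fell, 9 to 26 differed at least 2-fold, and 5 to 9 lists passed. Causes other than for no filter were not tested.

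The mean of 18 of 30 lists lay on the other side of 0 under at least 1 alternative. Heat shock, past the threshold in some fits, is the 1 of these that passed in any. Each mean covers the list members tested in that fit. With no filter, a strict filter, thinned libraries or a library left out, other genes were tested. Such a mean can therefore cover other members than the main fit. The cause of a change of side was not tested. With library totals alone the mean log2 fold change was, for oxygen sensing by the N-degron pathway -0.00587. With no filter the means were VQ motif family 0.0339, hypoxia response 0.00947, oxygen sensing by the N-degron pathway -0.0393, jasmonate synthesis and response 0.0948, phosphate starvation response 0.226, auxin response -0.0406, cell division -0.114, stomatal lineage 0.133, vascular tissue -0.000209, mitochondrial genome transcripts -0.101. With a strict filter they were aliphatic glucosinolates 0.0248, circadian clock -0.0206, heat shock and protein folding -0.0749, auxin response -0.0782. With limma-voom it was oxygen sensing by the N-degron pathway -0.00325. With thinned libraries they were hypoxia response 0.00207, aliphatic glucosinolates 0.00306, mitochondrial genome transcripts -0.0363. With a library left out the means ran as follows: oxygen sensing by the N-degron pathway -0.0508 to 0.0728, ethylene synthesis and response -0.0414 to 0.167, aliphatic glucosinolates -0.054 to 0.0432, cell division -0.0328 to 0.15, leaf senescence -0.0493 to 0.155, jasmonate synthesis and response -0.12 to 0.0309, stomatal lineage -0.147 to 0.0582, auxin response -0.0852 to 0.124, root endodermis and root tissues -0.0589 to 0.138, mitochondrial genome transcripts -0.0439 to 0.0634, phosphate starvation response -0.244 to 0.0609, hypoxia response -0.106 to 0.00805, rapid wound and elicitor response -0.0653 to 0.199, circadian clock -0.00722 to 0.159, mitochondrial stress response -0.158 to 0.145. At this depth genes with few counts, VQ1 and VQ10 among them, are tested only with no filter, where neither passed.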

Other observations

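The tests on root markers, library depth, noncoding RNA as a class, neighbouring genes and a chromosome segment were chosen after the results were seen, as was thinning the libraries. Of the 13 genes past the threshold 4 were noncoding RNAs, against 89 of the 12701 tested genes (two-sided Fisher's exact p = 1.5e-06, on a class chosen after its members were seen). A scan of 106 families of genes with the same product name, also chosen after the data were seen, called 0 with camera at the preset correlation and 0 with an estimated one.

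The 10 ways to split the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 13 genes and the highest other split 3 (1 of 10 splits with as many, the real one included). It gave 8 gene lists and the highest other split 11 (2 of 10 splits with as many).

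Per library, the scores of 6 of 30 lists (20%, where chance gives 10%) had separate ranges in the 2 genotypes: iron deficiency, abscisic acid, cold, sugar starvation, expansins and the VQ family. Each of these 6 had a two-sided exact permutation p of 0.1, the smallest that 3 against 3 can give. All 30 lists were scored on the same libraries and are not independent. The share of 20% against 10% therefore shows no excess by itself.

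Several explanations were weighed for the lower iron deficiency and abscisic acid lists and the higher sugar starvation list. A smaller share of the root tissues marked by the endodermis and root tissue list is argued against for iron alone. The 6 root markers had a mean log2 fold change of 0.0364, where the iron list had -0.76. The 2 SE interval of -0.19 to 0.26 covers the spread among these marker genes and not that between libraries. With a library left out, the root mean ran from -0.06 to 0.14 and the iron mean from -0.996 to -0.41. Root hair markers were too few to test, so a smaller share of root hairs stays open. With all libraries thinned to 1 total the means were -0.75 for iron, 0.59 for sugar starvation and -0.68 for abscisic acid. Thinning keeps each gene's expected share of a library, so the means had to stay close. It therefore does not decide whether library depth plays a part. A harvest at another time of day stays open, though the labels give 4 h after lights on for all libraries. CCA1 and LHY, clock genes of the morning, against the later GI and PRR7 gave a log2 contrast of -0.37 (95% interval -0.69 to -0.04). This interval excludes 0, while a contrast beyond 0.5 in size was needed to call it. The interval takes the 4 genes as independent and leaves out changes that they share within a library. PRR5 and TOC1, also planned for the contrast, were not among the tested genes. The genotype is among the open explanations too, untested apart from the comparison itself.

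For the 4 noncoding RNAs, a lower yield of noncoding RNA as a class is argued against by the median log2 fold change of the other tested noncoding RNAs, -0.00647 (bootstrap 95% interval -0.05 to 0.05). Reads or readthrough from neighbouring genes are argued against for AT2G01422 alone, which had a log2 fold change of -4.58, while the lower of its 2 direct neighbours, HB17, had -0.60 (2 SE interval -1.46 to 0.26); for the other 3 this stays open, since 5 of their 6 direct neighbours were not tested. A single chromosome segment from another background cannot hold all 13 genes, since they lay on 5 chromosomes. Whether a segment holds some of them is not decided. Of their 78 pairs 0 lay within 50 annotated genes of each other, and the nearest pair was 100 genes apart. A longer segment, or a segment with 1 called gene, would give no closer pair. Also open are an effect of the amiRNA on VQ1 and VQ10, an effect on other transcripts, and a difference inherited in the line by itself. A single genotype against wild type does not separate these. No search for other targets of the amiRNA was run, since its sequence is not given in the sources used here.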
